A study of Mus musculus with 6 samples.

How the data were processed

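Oviducts of MF1 mice, an outbred stock, were compared between 3 wild-type and 3 Wt1 heterozygous samples. Per the labels, the females had been mated with wild-type males, the oviducts were taken at embryonic day 2.5, and biotin-labelled cRNA was prepared from 1 µg of total RNA. Group and replicate number came from the sample titles and genotype labels. The labels do not say whether the 3 samples of a genotype came from separate animals or pools, so p-values measure the spread between these samples, which may be technical in part.

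The authors deposited 1 linear intensity per probe set and array, for 45101 probe sets of a 1-colour 3' expression array. The program that summarised the probes is not given in the sources used here. In all 6 arrays the mean intensity after removing 2% of probe sets at each end was 500.002, so the deposited values had been scaled to a common mean; this was found from the values. No detection calls were used, so whether a dim probe set lay above background is unknown. The number of arrays limits the precision of every value.

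The 64 control probe sets were left out, which left 45037. Intensities under 1 were set to 1 and log2 transformed. The array medians differed by 0.147 on the log2 scale, more than the limit of 0.1 set before the data were examined, so the arrays were quantile normalized; the deposited scaling was kept as an alternative. Of the tested probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were not listed there and stay unnamed here. Entrez identifiers of 34741 of the probe sets with 1 symbol matched the RefSeq gene table, and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean over all 6 arrays; 9010 genes had several probe sets. No genome build is named in the files, so no coordinates are given.

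Differences, as heterozygous minus wild type, were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, over probe sets and again over genes. Errors beside log2 changes are the moderated standard errors of limma. Errors beside group means are SDs over 3 arrays. Single values were also compared by an exact two-sided permutation test, for which 3 arrays against 3 give 20 assignments and a smallest p of 0.1. Gene lists with at least 5 measured members were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over 34 lists. The lists, tests, alternatives and rule for naming genes were fixed before the data were examined.

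The naming rule took Wt1, up to 12 rises and 12 falls past the threshold without overlap between the groups and with a higher group mean above the median of all probe sets (7.31 on the log2 scale), and, where fewer than 8 passed in a direction, the genes of smallest p with a log2 change of at least 0.58 and the same conditions, up to 8. It also took up to 4 members per list that passed over all genes or over the list alone, or the 2 of smallest p in the direction of a list that passed, and Prss29, a protease recalled from the study's paper. The protease lists are for that reason not independent of these samples. Genes named outside this rule were chosen after their values were seen, and are marked as such.

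Alternatives were the deposited scaling, a filter on dim probe sets, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each array, other rules for probe sets and log2 of the intensity plus 16. The ratio of 3' to 5' control probe sets, as a covariate and as a block of 2 classes, was added after the data were seen, as was log2 of the intensity plus 16 for genes, lists and Wt1. The scripts were tested on simulated data built from the means and spreads of the 18193 genes. Of 100 genes shifted by 1 on the log2 scale 30% were recovered, and of 100 shifted by 2 on that scale 74%, with 11 false calls. Over 20 further draws, false calls numbered 5.7 on average, a mean share of 5.38% of the calls. A list shifted by 0.4 was called with the preset correlation (adjusted p = 8.45e-14) and with an estimated one (adjusted p = 0.0320). In that simulation 1 of 33 unshifted lists was called with the preset correlation and 0 with the estimated one. Its noise was drawn independently for each gene, so these list calls do not cover lists whose genes vary together.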

Results

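Gene expression was measured in oviducts of MF1 mice at embryonic day 2.5, in 3 wild-type and 3 Wt1 heterozygous samples, with 1 array per sample. Wt1 encodes a zinc finger transcription factor, and the comparison asks how the loss of 1 allele alters oviductal transcripts while embryos are in transit. The median intensity lay between 152.0 and 168.3 over the arrays. Correlations between arrays ranged from 0.960 to 0.972 across genes, with a mean of 0.966 within genotypes and 0.965 between them.

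RNA quality differed between arrays. The 3' to 5' intensity ratio of the Actb control was 1.74, 2.40 and 5.90 in wild-type replicates 1, 2 and 3, and 2.49, 1.67 and 1.71 in heterozygous replicates 1, 2 and 3. The Gapdh ratio was likewise highest in wild-type replicate 3, at 2.39, against 0.740 to 1.07 in the other arrays. The 3 arrays with the higher ratios, wild-type replicates 2 and 3 and heterozygous replicate 1, also had the highest scores on the leading principal component, which held 27.2% of the variance. Neither ratio separated the genotypes (exact permutation p = 0.4 for Actb and 0.6 for Gapdh).

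The Wt1 transcript was measured by 1 probe set. Its mean was 11.96 ± 0.26 (SD, n = 3) in wild-type and 11.39 ± 0.35 (SD, n = 3) in heterozygous oviducts, 1.48-fold lower, a log2 change of -0.57 with a standard error of 0.24. Intensities were 4526, 4246 and 3323 in wild-type replicates 1, 2 and 3, and 2253, 2452 and 3468 in heterozygous replicates 1, 2 and 3. The array labelled heterozygous replicate 3 thus lay above wild-type replicate 3, and the groups overlapped. The difference did not pass the threshold (limma p = 0.0591, adjusted p = 0.933 over probe sets, exact permutation p = 0.2). In the limma fit over genes the p was 0.0493 and the adjusted p 0.771. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, so its level is a weak check of the labels. Within the 3 arrays of lower and the 3 of higher 3' to 5' ratio the Wt1 change was -0.64 and -0.74.

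Across 18193 genes, 3 fell in heterozygous oviducts and 0 rose past the threshold. Hmx2, a homeobox gene, fell by 2.45 on the log2 scale (standard error 0.14, adjusted p = 0.0283). Rbfox1, a splicing regulator, fell by 2.20 (standard error 0.13, adjusted p = 0.0283), and Rhpn1 fell by 1.92 (standard error 0.13, adjusted p = 0.0323). All 3 means were below the median of all probe sets in both genotypes, and these genes are named because the count is small, after their values were seen. The other 3 probe sets of Rbfox1 gave log2 changes of 0.15, 0.81 and -0.55. With the mean of its probe sets the gene Rbfox1 stood at -0.45 and did not pass (adjusted p = 0.913). With log2 of the intensity plus 16 the gene Hmx2 stood at -1.24 and did not pass (adjusted p = 0.0570). With trend and robust the standard errors were larger, at 0.48, 0.30 and 0.34 for Hmx2, Rbfox1 and Rhpn1. None of these 3 passed there (adjusted p = 0.194, 0.0560 and 0.154). With limma the count was 0 when any array was left out, wild-type replicate 3 included, with 849 to 1906 genes at an unadjusted p under 0.05. Genes of smallest p have little spread within groups, so leaving out 1 array can hardly move them. The changes thus stayed about as large in these fits, which is no separate support. They ranged from -2.54 to -2.37 for Hmx2, from -2.27 to -2.16 for Rbfox1 and from -1.96 to -1.84 for Rhpn1. At an unadjusted p under 0.05 there were 1171 genes, 485 higher and 686 lower, where 910 would arise by chance. The groups did not overlap in 2141 genes, 11.8%, where chance gives 10%.

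Among 45037 probe sets, 3 passed, each with an adjusted p of 0.0270. A Cnnm1 probe set rose by 2.97 on the log2 scale, from a mean of 2.38 to 5.35, a dim range. With log2 of the intensity plus 16 its log2 change was 1.42 and it did not pass (adjusted p = 0.154). Both others have no gene name in the annotation used. A dim one lay at about the floor of 1 in all 3 heterozygous arrays, so the size of its difference was set by the floor, and with log2 of the intensity plus 16 it was -0.82 and did not pass (adjusted p = 0.375). Another fell by 2.63 on the log2 scale. The last was bright, at 10.61 ± 0.09 (SD, n = 3) in wild-type and 7.98 ± 0.07 (SD, n = 3) in heterozygous oviducts. It passed with the deposited scaling (adjusted p = 0.0320), the filter on dim probe sets (0.00131) and trend and robust (0.00102). It also passed with array weights (0.0114), log2 of the intensity plus 16 (0.0167) and without cross-hybridizing probe sets (0.0248). It did not pass when any array was left out (adjusted p = 0.155 to 0.328) or with the replicate number as a block (0.996). Nor did it pass with the 3' to 5' ratio as a covariate (0.172) or block (0.221). Without wild-type replicate 3, 1 other probe set passed and none of these 3 did (adjusted p = 0.163 each). With all arrays there were 2334 probe sets at an unadjusted p under 0.05.

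None of the brighter genes passed the threshold, and those given here were chosen for a small p and no overlap between the groups. Cxcl15, a chemokine, had a mean of 7.72 ± 0.33 (SD, n = 3) in wild-type and 10.22 ± 0.13 (SD, n = 3) in heterozygous oviducts, 5.66-fold higher (log2 change 2.50, standard error 0.20, adjusted p = 0.0620 with limma). It was higher in each heterozygous array than in every wild-type array, and its other probe set gave a log2 change of 2.03. The log2 change was 2.80 and 2.30 within the arrays of lower and higher 3' to 5' ratio. Cxcl15 passed the threshold with the filter on dim probe sets, with trend and robust, with array weights, with the mean of its probe sets and with log2 of the intensity plus 16. Over all alternatives the adjusted p of the gene Cxcl15 ranged from 0.00399 to 0.609.

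Among genes with a higher group mean above the median of all probe sets, the others of smallest p on the higher side were Mvk, mevalonate kinase of cholesterol synthesis, at a log2 change of 1.89, Cd99, a surface glycoprotein, at 1.16, Lbh at 1.14 and Dusp19, a phosphatase, at 1.13. Pdlim3, an actin-associated protein of muscle, stood at 1.04, Slco4c1, an organic anion transporter, at 1.01 and Tcf21, a mesenchymal transcription factor, at 0.68. Their adjusted p ranged from 0.181 to 0.387. All 3 probe sets of Cd99 were higher, by 1.02 to 1.31, whereas the mean over the Slco4c1 probe sets turned negative. Other probe sets gave smaller or opposite changes with overlap between the genotypes: 0.24 and 0.21 for Lbh, the first about as bright as the named one, -0.70 for Dusp19, whose remaining one gave 1.00, 0.11 for Tcf21 and 0.90 for Mvk. Among the lower genes chosen in the same way the log2 change was -2.67 for Sh3tc2, -2.30 for Rbm45, an RNA-binding protein, and -1.68 for Pkp1, a desmosomal plakophilin. It was -1.41 for Tfap2c, a transcription factor, -1.23 for Slc6a2, the noradrenaline transporter, -1.22 for Trank1, -1.09 for Sec14l3, a lipid-binding protein, and -0.93 for Banp. Their adjusted p ranged from 0.201 to 0.266. The probe sets of Tfap2c and of Sec14l3 were all lower, 3 for each gene, whereas the other probe sets of Slc6a2 gave -0.11, -0.45 and -0.25.

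**Figure D1:**
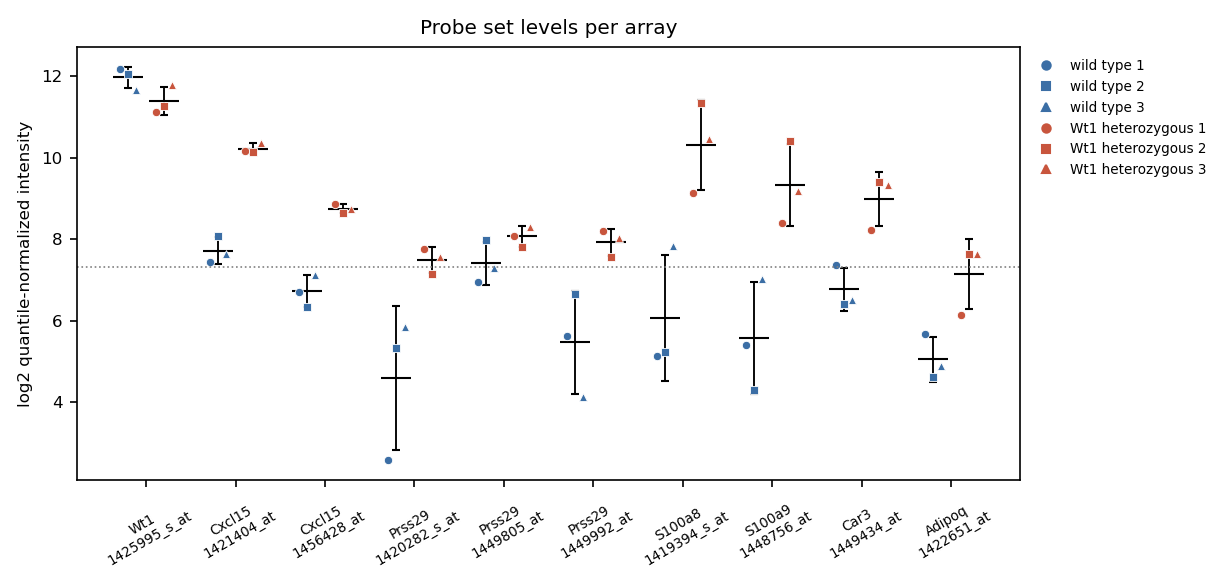
Log2 quantile-normalized intensity of 10 probe sets in each of the 6 arrays, with wild-type arrays in blue and heterozygous arrays in red, the marker shape giving the replicate number, black bars the mean ± SD of 3 arrays and the dotted line the median of all probe sets (7.31). Wt1 overlapped between the genotypes, while both Cxcl15 probe sets did not.

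Proteases were listed because Prss29 was recalled from the study's paper, so these lists are not independent evidence. Prss29, a secreted serine protease, gave a log2 change of 0.65 (standard error 0.29) at its brightest probe set, where the genotypes overlapped (adjusted p = 0.809 over genes). The value for the gene Prss29 was 0.42 without wild-type replicate 1 and 0.25 with array weights. Its brightest probe set gave 0.94 without wild-type replicate 2. At its dimmer probe sets the genotypes did not overlap, with log2 changes of 2.46 and 2.90 and adjusted p of 0.797 and 0.861 over probe sets. The first was 1.80 without wild-type replicate 3 and 3.05 without wild-type replicate 2. The second was 1.88 without wild-type replicate 1 and 3.55 without wild-type replicate 3. Prss28 had a log2 change of 1.63 at very low levels, from 2.23 to 3.86. The 46 measured secreted serine proteases did not pass as a list (camera adjusted p = 0.769, median log2 change -0.02, 21 members higher and 25 lower), and no member passed over all genes or adjusted over the list alone. The median was -0.22 without wild-type replicate 1 (adjusted p = 0.237), 0.11 without wild-type replicate 2 (0.0758) and 0.12 with the classes of 3' to 5' ratio as a block (0.0589). It was 0.07, 0.02 and 0.01 without wild-type replicate 3, heterozygous replicate 2 and heterozygous replicate 3, and -0.06 without heterozygous replicate 1.

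Of the 33 measured metalloproteases, 24 were higher, with a median log2 change of 0.25. The list passed with camera (adjusted p = 2.35e-04), though adjusted p = 0.275 with an estimated correlation. Mmp7, a matrix-degrading enzyme, had a log2 change of 0.62 and Anpep, an aminopeptidase, of 0.51; 0 members passed over all genes and 0 adjusted over the list alone. Without wild-type replicate 3 the median of the metalloprotease list was 0.13. Of the 32 protease inhibitors, 20 were higher, and the list did not pass (adjusted p = 0.0678). It passed without wild-type replicate 2 (adjusted p = 0.0441), without heterozygous replicate 3 (0.0492), with the filter on dim probe sets (0.00221) and with trend and robust (0.0288).

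Markers of muscle, vessels, stroma and fat were higher in heterozygous oviducts. Of 23 smooth muscle genes 19 were higher, by a median of 0.39 (camera adjusted p = 7.92e-07, but adjusted p = 0.604 with an estimated correlation). Actg2, smooth muscle gamma actin, had a log2 change of 0.84 and Casq2, a calcium-binding protein, of 0.86. Casq2 means were below the median of all probe sets in both genotypes. The list's score per array overlapped between the genotypes: it was -0.25, -0.25 and -0.04 in wild-type replicates 1, 2 and 3, and 0.18, 0.43 and -0.07 in heterozygous replicates 1, 2 and 3. Without heterozygous replicate 3 the smooth muscle median was 0.61. Of 21 endothelial genes 19 were higher, by a median of 0.29 (adjusted p = 2.10e-05, and adjusted p = 0.484 with an estimated correlation), with Pecam1 at 0.83 and Sox18 at 0.36. In the stromal fibroblast list 19 of 27 genes were higher, by a median of 0.13 (adjusted p = 0.00117, and adjusted p = 0.604 with an estimated correlation), with Tcf21 past the threshold adjusted over the list alone (0.0288) and Postn, a matrix protein, at 0.67. The stromal call was lost without heterozygous replicate 2 (adjusted p = 0.168, median 0.06), and the median was 0.20 without heterozygous replicate 3. Stromal scores per array also overlapped between the genotypes (exact permutation p = 0.2).

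The adipocyte list had 11 of 15 genes higher, by a median of 0.20 (adjusted p = 0.00592, and adjusted p = 0.484 with an estimated correlation). Car3 (log2 change 2.22), Adipoq (2.08) and Fabp4 (1.48) passed adjusted over the list alone, and 0 passed over all genes. Their wild-type means were below the median of all probe sets, and the Adipoq mean was below it in both genotypes. Adipoq encodes the fat hormone adiponectin. The other probe sets of Fabp4 gave 2.37, 0.20 and -0.08, and those of Car3 gave 0.95, 0.63 and 0.55, the last 2 with overlap between the genotypes. Fat next to the oviduct was 1 of the neighbouring tissues the lists were chosen to cover. The list lost its call without wild-type replicate 3 (adjusted p = 0.0522), without heterozygous replicate 2 (0.0913, median 0.13), without cross-hybridizing probe sets (0.0740) and with the 3' to 5' ratio as a covariate (0.0635). The uterine epithelium list passed (adjusted p = 0.0228, and adjusted p = 0.484 with an estimated correlation), with 12 of 20 genes higher and Cxcl15 past the threshold adjusted over the list alone (3.07e-04). Its mean was 0.32 and its median 0.16, with Cxcl15 at 2.50 and Prss28, at very low levels, at 1.63. The list held 19 genes besides Cxcl15, 11 higher and 8 lower, with a median of 0.14. It lost its call without wild-type replicate 1 (adjusted p = 0.118), without heterozygous replicate 2 (0.0814), with array weights (0.116) and with the 3' to 5' covariate (0.0635). The leukocyte list passed with 23 of 34 genes higher and a median of 0.09 (adjusted p = 0.0238, and adjusted p = 0.719 with an estimated correlation), led by Jchain, of plasma cells, at 0.86 and Klrk1, of natural killer cells, at 0.60. Its call was lost without wild-type replicate 1 (adjusted p = 0.298), wild-type replicate 2 (0.245) or heterozygous replicate 2 (0.328), without cross-hybridizing probe sets (0.119) and with the mean of a gene's probe sets (0.122). Its median was 0.01 without wild-type replicate 1, 0.24 without wild-type replicate 3, 0.04 without heterozygous replicate 2 and 0.14 without heterozygous replicate 3, and the gene Klrk1 stood at 0.34 without wild-type replicate 1. Klrk1 means were below the median of all probe sets in both genotypes.

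**Figure D2:**
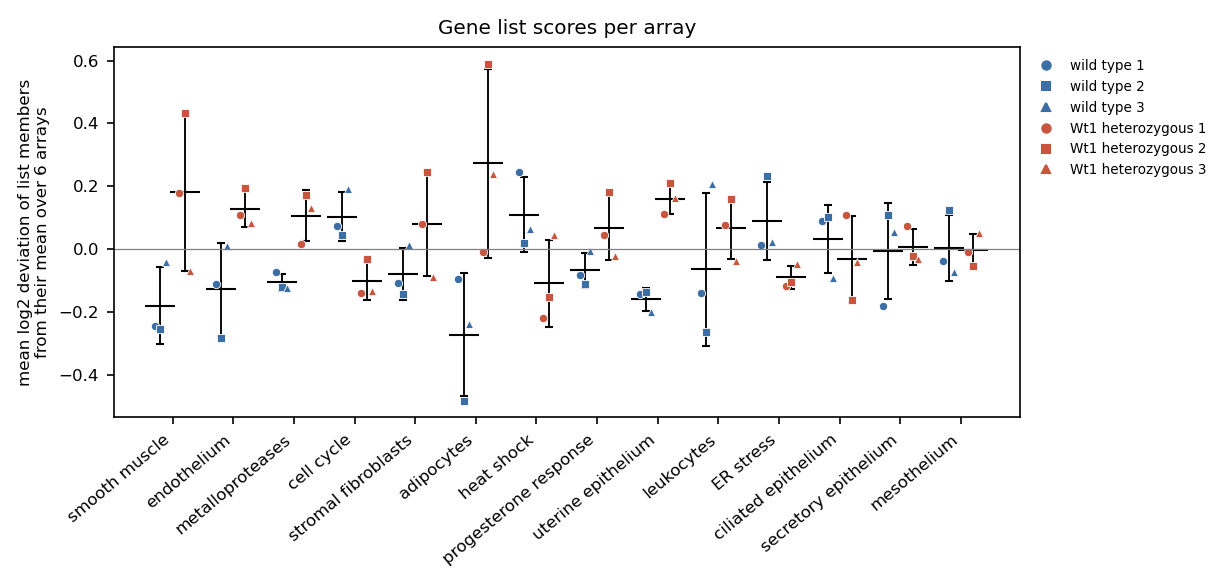
Mean log2 deviation of the members of 14 gene lists from their mean over 6 arrays, for wild-type arrays in blue and heterozygous arrays in red, the marker shape giving the replicate number and black bars the mean ± SD of 3 arrays. Uterine epithelium and metalloprotease scores were higher in each heterozygous array than in every wild-type array. Scores of smooth muscle, stromal fibroblasts, leukocytes, heat shock and progesterone response overlapped, as did those of ciliated epithelium, secretory epithelium and mesothelium.

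**Figure D3:**
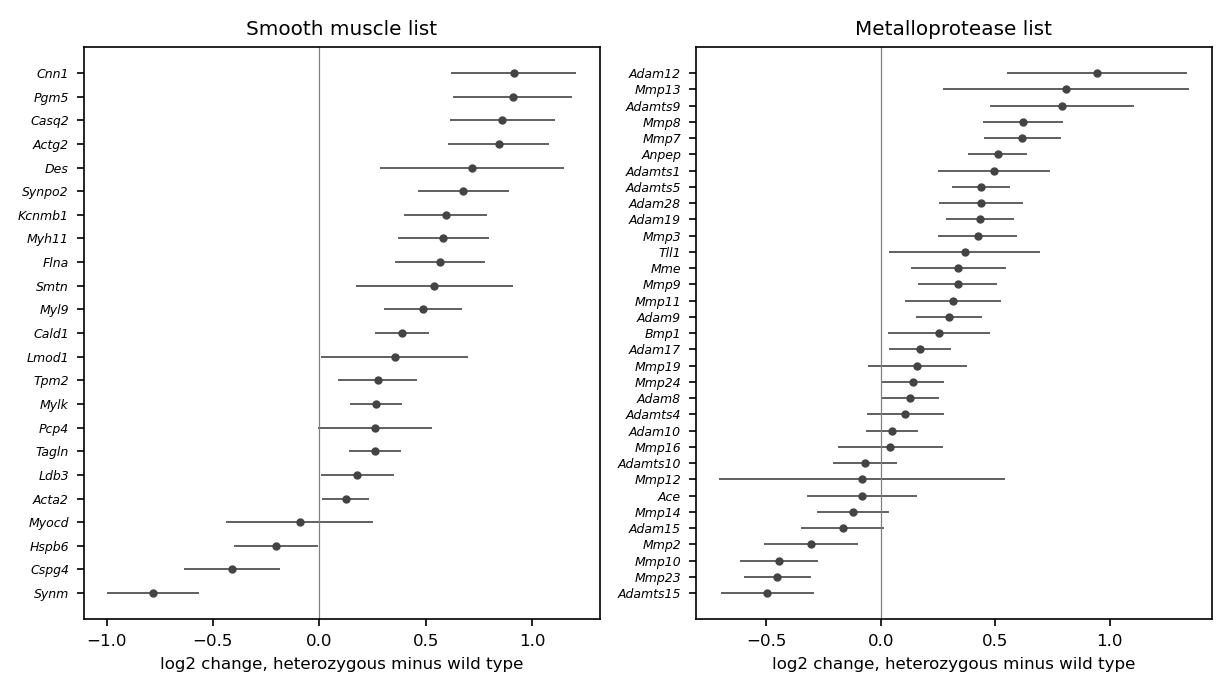
Log2 change, heterozygous minus wild type, with its standard error, of each measured gene of the smooth muscle list (23 genes) and of the metalloprotease list (33 genes). In the smooth muscle list 19 genes lie above 0 and in the metalloprotease list 24.

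Cell division and chaperone genes were lower. Of 37 cell cycle genes 32 were lower, by a median of -0.19 (adjusted p = 0.00117, and adjusted p = 0.484 with an estimated correlation). Among them Cdca8 stood at -0.75 and Aurkb, a mitotic kinase, at -0.70. The other Aurkb probe set was higher by 1.18, without overlap, and the mean over the Aurkb probe sets turned positive. Both Aurkb probe sets had means below the median of all probe sets. The other Cdca8 probe sets gave -0.54 and -0.15, with overlap. The call was lost with array weights (adjusted p = 0.0608) and with the mean of a gene's probe sets (0.264), and the median was -0.08 without wild-type replicate 3. Of 18 heat shock genes 16 were lower, by a median of -0.19 (adjusted p = 0.00592, and adjusted p = 0.604 with an estimated correlation), with Dnajb1, a cochaperone, at -0.86 and Chordc1 at -0.57; the other Dnajb1 probe set gave -0.46, with overlap. The heat shock call was lost without wild-type replicate 1 (adjusted p = 0.347, median -0.12), without heterozygous replicate 1 (0.124), with array weights (0.0584) and with the mean of a gene's probe sets (0.122). Heat shock scores per array overlapped between the genotypes (exact permutation p = 0.2). The list of the unfolded protein response of the endoplasmic reticulum passed downward (adjusted p = 0.0385, and adjusted p = 0.633 with an estimated correlation), with 15 of 26 genes lower and a median of -0.06. Its genes Ddit3 and Chac1, both induced by stress, stood at -0.70 and -0.69, with the other Ddit3 probe set at -0.33, with overlap. This call was lost without wild-type replicate 1 (adjusted p = 0.120), wild-type replicate 2 (0.403), heterozygous replicate 1 (0.137) or heterozygous replicate 2 (0.0829), with the replicate number as a block (0.0521), without cross-hybridizing probe sets (0.0859) and with the mean of a gene's probe sets (0.128). Its median was -0.13 without wild-type replicate 1, wild-type replicate 3 or heterozygous replicate 1, and -0.03 without wild-type replicate 2.

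In the progesterone response list 14 of 22 genes were higher, by a median of 0.15 (adjusted p = 0.0125, and adjusted p = 0.484 with an estimated correlation), with Errfi1 at 0.57 and Fst, follistatin, at 0.56 (1.30 and 0.37, with overlap, at their other probe sets). The progesterone call was lost without wild-type replicate 2 (adjusted p = 0.0649), without heterozygous replicate 2 (0.168, median 0.10) and with the classes of 3' to 5' ratio as a block (0.0526). Progesterone response scores per array overlapped between the genotypes (exact permutation p = 0.2). The estrogen response list did not pass (adjusted p = 0.774). The inflammation list did not pass (adjusted p = 0.0678); its median was -0.01 while its mean was 0.33, and it passed without wild-type replicate 3 (adjusted p = 0.0226), with the filter on dim probe sets (6.03e-04), with trend and robust (0.0115) and with the 3' to 5' ratio as a covariate (0.0308) or block (0.0496). The calcium-binding proteins S100a8 and S100a9 of myeloid cells were 18.9-fold and 13.6-fold higher (log2 change 4.24 with a standard error of 0.90, and 3.76 with one of 0.81). These folds rest on low wild-type intensities, 33.3, 37.3 and 222.6 for S100a8 and 39.8, 19.9 and 129.6 for S100a9 in replicates 1, 2 and 3. Without wild-type replicate 3 the log2 changes were 5.14 for the gene S100a8 and 4.50 for the gene S100a9, and without wild-type replicate 2 the latter was 3.12. Within the arrays of lower and higher 3' to 5' ratio they were 5.76 and 2.61 for S100a8, and 4.40 and 2.74 for S100a9. Both, with Ccl28 at 0.89 (1.33 and 0.66, with overlap, at its other probe sets) and Hp, haptoglobin, at 0.54, passed adjusted over the list alone (0.0450 each) and not over all genes. Single members also passed adjusted over the list alone in lists that did not pass with camera: Mvk in cholesterol synthesis (0.00186), and in mucins and glycosylation the sialyltransferase St6gal1, with a log2 change of -0.74 (0.0196) and of -0.18, with overlap, at its other probe set, and B3gnt5, at 0.83 (0.0405).

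In all, 11 of 34 lists passed with camera at the preset correlation, 8 higher and 3 lower. With an estimated correlation 0 passed (2 at an unadjusted p under 0.05), and with fry, which tests whether the genes of a list move on balance 1 way, 0 passed (lowest adjusted p = 0.0904, with 3 at an unadjusted p under 0.05). Tested for change in either direction with fry, 10 lists passed, 5 of them among the 11 (smooth muscle, metalloproteases, stroma, adipocytes and uterine epithelium) and 5 that did not pass with camera (mucins and glycosylation, complement, mesothelium, ovarian somatic cells and cholesterol synthesis). Each of the 11 lists kept the sign of its mean within the arrays of lower and of higher 3' to 5' ratio, each class holding 1 array of one genotype and 2 of the other; the smooth muscle mean was 0.43 and 0.33. Ciliated epithelium, with 33 of 43 genes lower, did not pass (adjusted p = 0.0557). It passed downward without wild-type replicate 3 (adjusted p = 4.84e-04), without heterozygous replicate 1 (0.00365), with the deposited scaling (0.0230), with the filter on dim probe sets (0.0139) and with trend and robust (0.0115). It also passed with array weights (0.00148), with log2 of the intensity plus 16 (0.0497) and with the 3' to 5' covariate (0.00497). Its mean was -0.19 within the arrays of lower 3' to 5' ratio and 0.10 within those of higher ratio, and with these classes as a block it did not pass (adjusted p = 0.184). Immediate early genes did not pass (adjusted p = 0.0678) and turned downward without heterozygous replicate 1 (median -0.15, adjusted p = 0.741). They passed upward without heterozygous replicate 2 (0.0122) or heterozygous replicate 3 (0.0137), with the filter on dim probe sets (0.0425), with trend and robust (0.0433) and with the 3' to 5' block (0.00801). Nor did secretory epithelium (adjusted p = 0.769), mesothelium (0.908) or published Wt1 target genes (0.334) pass. The camera direction was upward and both the median and the mean were negative for secreted serine proteases, mesothelium, red blood cells and ovarian somatic cells. For oocyte and embryo genes the median was negative and the mean and direction positive, and for cholesterol synthesis the mean was positive and the median and direction negative. None of these 6 lists passed with camera, though the ovarian list passed upward with the filter on dim probe sets (median 0.24, adjusted p = 0.0441). Leaving out heterozygous replicate 2 gave 6 lists past the threshold, 5 of them among the 11. Leaving out wild-type replicate 1 gave 7, all among the 11.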

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

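The 3' to 5' ratio as a covariate and as a block of 2 classes, and log2 of the intensity plus 16 for genes, lists and Wt1, were tests chosen after the data were seen. Wt1 kept its direction and stayed short of the threshold in every alternative run. With all arrays 3 probe sets, 3 genes and 11 lists passed. Array weights gave 14 probe sets and 7 genes, including the 3. A threshold of 0.1 gave 10 probe sets and 7 genes. The filter on dim probe sets gave 1 gene and trend with robust gave 1, in each case Cxcl15 and none of the 3. Log2 of the intensity plus 16 gave 1 probe set and 2 genes, Rbfox1 and Cxcl15. Hmx2 (adjusted p = 0.0570) and Rhpn1 (0.0557) lost their calls with it. Without probe sets whose identifiers mark possible cross-hybridization 0 genes passed with limma (1034 at an unadjusted p under 0.05). Hmx2 and Rhpn1 kept their changes of -2.45 and -1.92 there (adjusted p = 0.0562 each), while Rbfox1 stood at -0.55. Both the 3' to 5' covariate and the 3' to 5' block gave 0 probe sets and 0 genes (1143 and 1171 genes at an unadjusted p under 0.05), though Hmx2, Rbfox1 and Rhpn1 were still lower, by log2 changes of -2.52, -2.14 and -1.96 and of -2.46, -2.17 and -1.94. Leaving out 1 array gave 0 to 1 probe sets, 0 genes and 6 to 13 lists. Leaving out wild-type replicate 3 gave 1 probe set, none of the 3 that passed with all arrays (adjusted p = 0.163 each), and any other array 0. Each of the 6 arrays thus moved the counts of probe sets and genes by over 1.5 times. These fits had 3 in place of 4 residual degrees of freedom. The changes held, which the small spread within groups of genes picked by p makes likely, so this is no separate support. They ranged from -2.54 to -2.37 for Hmx2, from -2.27 to -2.16 for Rbfox1 and from -1.96 to -1.84 for Rhpn1. The list count fell to 7 without wild-type replicate 1 and to 6 without heterozygous replicate 2. The mean of a gene's probe sets gave 7 lists, and camera with an estimated correlation and fry gave 0 each. With that mean Slco4c1 turned to -0.17 and Aurkb to 0.24. The share of genes near Wt1 at an unadjusted p under 0.05 was 12.1% with the filter on dim probe sets, which tests fewer genes. In the other cases the cause was not tested. Over the named genes, 720 of the values under alternatives kept direction and side of the threshold, 38 lost the threshold, 8 gained it and 2 turned. Over the 11 lists 138 values kept both and 49 lost the threshold, 11 of these with an estimated correlation and 11 with fry. These tallies leave out the setting without cross-hybridizing probe sets, in which 8 of the 11 lists passed. Dim signal limits the probe sets near the floor, since whether they lay above background is unknown.

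The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.10, -0.03 and -0.08 across genes, and 0 of the 6 arrays correlated best with its own number. With the replicate number as a block 0 probe sets, 0 genes (976 at an unadjusted p under 0.05) and 10 lists passed.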

Other observations

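The tests on Cxcl15 and on the smooth muscle list and the fits with the 3' to 5' ratio were chosen after the results were seen. Genes named in this paragraph were also chosen after their values were seen. Ovgp1, the oviductal glycoprotein of secretory cells, had a log2 change of 0.06 (standard error 0.10). Mesothelial markers went both ways, with Lrrn4 at 0.84 (standard error 0.23) and Ildr2 at -1.01 (standard error 0.34), and 8 of 18 were higher. Among ciliated cell genes Foxj1, their master regulator, stood at -0.31 (standard error 0.13) and Ccno, which drives centriole amplification, at -0.87 (standard error 0.25). The immediate early genes, which respond to tissue handling, scored 0.48 in heterozygous replicate 1 and between -0.20 and -0.03 in the other 5 arrays.

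Genes near Wt1 on chromosome 2 were at an unadjusted p under 0.05 in 7 of 47 cases, 14.9%, against 6.41% of other genes (Fisher's exact test, two-sided, p = 0.0295). With the filter on dim probe sets 4 of 33 were (Fisher's exact test, p = 0.328). They included Cd59a at a log2 change of -0.53, Rcn1 at -0.46 and Commd9 at 0.63, and 0 of the 7 passed over all genes, with adjusted p from 0.427 to 0.768.

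The 6 arrays can be split into equal groups in 10 ways, too few for a share under 0.05. The genotypes gave 3 probe sets, 3 genes and 11 lists, and the highest values of the other splits were 3, 1 and 8. Thus 2 of the 10 splits gave as many probe sets, 1 as many genes and 1 as many lists. The other split with 3 probe sets set the 3 arrays of lower 3' to 5' ratio against the 3 of higher ratio. It gave 2114 genes at an unadjusted p under 0.05 against 1171 for the genotypes, so the arrays have a structure along RNA quality. With these classes as a block 0 probe sets, 0 genes and 12 lists passed for the genotypes. The changes of the 3 genes stayed about as large: -2.45, -2.20 and -1.92 for Hmx2, Rbfox1 and Rhpn1 (standard errors 0.14, 0.13 and 0.13) became -2.46, -2.17 and -1.94 with the block (0.16, 0.14 and 0.13). Their calls ended (adjusted p = 0.162 each) with 3 in place of 4 residual degrees of freedom. Within the classes of lower and higher ratio they were -2.41 and -2.51, -2.04 and -2.30, and -2.11 and -1.76. The genes were picked by small p, so their spread within groups was small and such stability is no separate support.

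Cxcl15 was 5.66-fold higher in heterozygous oviducts. Its log2 change was 2.45 without wild-type replicate 3, which argues against that array's RNA as the cause, and 2.03 at its other probe set, which argues against a probe set fault. Uterine tissue carried over is a candidate source, since uterine glands express Cxcl15. The other 19 uterine genes had a median log2 change of 0.14, with 11 higher and 8 lower and a range from -1.22 to 1.63. The highest was Prss28, also a member of the uterine list, at very low levels. Only 2 of the 19 were measured in the range that would show a small share, so carried-over tissue stays open. An effect of genotype stays open as well, as a hypothesis.

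S100a8 and S100a9 were higher by 4.24 and 3.76 on the log2 scale. Wild-type replicate 3 had the highest wild-type values of both genes, at 7.84 and 7.03. More neutrophils are a candidate source: of 30 other neutrophil genes listed before the test 23 were measured, with 15 higher and a median log2 change of 0.18 (camera p = 0.00469, p = 0.212 with an estimated correlation). Mpo, at 1.11, Ngp, at 2.21, and Chil3, at 2.08, were the 3 at an unadjusted p under 0.05. Mpo and Ngp were among the 9 of the 23 with means above the median of all probe sets. The brightest of these were Anxa1 (0.03), Hdc (0.18) and Lcn2 (0.21), at levels where a small share of neutrophils would hardly show. Below the median, Camp stood at 2.42 and Elane at 1.51, both with overlap, and 8 of the 23 were lower. Ngp was 7.30, 10.19 and 9.71 in heterozygous replicates 1, 2 and 3, against at most 7.16 in wild-type arrays. Neither more neutrophils nor induction in other cells can be excluded, and an effect of genotype stays open.

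The smooth muscle list was higher by a median of 0.39. Its camera adjusted p ranged from 4.55e-10 to 0.00104 over the alternatives at the preset correlation. With an estimated correlation the list did not pass (adjusted p = 0.604), nor with fry (0.364). A lower share of epithelium, which would raise other cell types alike, stays open. The smooth muscle median lay above those of all 6 other lists, with an adjusted permutation p under 0.05 for 3. These 3 were stromal (0.13, adjusted permutation p = 0.0208), leukocyte (0.09, 0.00366) and mesothelial (-0.03, 0.0208). The permutation was over genes, which are not independent replicates. The smooth muscle median lay only 0.0934 above the endothelial one (0.436), with adipocytes at 0.20 (0.524) and neurons at -0.02 (0.0525). Muscle content that differed between dissected oviducts regardless of genotype may account for it, since scores overlapped (exact permutation p = 0.2), and this cannot be told apart from an effect of genotype with 3 arrays per group.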
